A study of Mus musculus with 12 samples.

How the data were processed

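Total RNA from 12 samples of Min6 cells, 6 infected with sh-ctrl adenovirus and 6 with sh-Il22ra1 adenovirus, was extracted with TRIzol, made into libraries with the VAHTS Universal V6 kit and sequenced as paired ends on a NovaSeq instrument, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, which carry GFP for sh-ctrl and shRNA for sh-Il22ra1. The treatment labels of sh-Il22ra1 replicates 2 to 6 give the gene name with an increasing last number, and these samples were kept in the group of their titles. HISAT2 2.0.5, HTSeq and the mm10 build are named in the submitters' processing notes; the annotation, the strand setting and other counting options are not given in the sources used here.

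Each deposited sample file holds whole-number read counts for 24421 gene symbols plus 5 rows of reads that were not assigned to genes; these are counts by their values, and HTSeq is the counter per the submitters' processing notes. A deposited table of the whole series holds CPM (counts per 1e+06 reads, with the rows of unassigned reads included): its columns each sum to 1e+06, and multiplying by the column totals of the count files gave whole reads, within a tolerance of 0.001, for 100% of values. The rows that name no gene were left out of library sizes and tests. Across libraries they took 12.8% to 17.3% of sh-ctrl files and 8.71% to 11.8% of sh-Il22ra1 files for reads without an alignment, and on average 3.84% and 4.05% for reads outside annotated exons, 1.87% and 2.07% for ambiguous reads, 4.44% and 4.80% for low alignment quality and 3.96% and 4.22% for multiple alignments. Reads in genes totalled 13108494 to 15887448 per library, and the biological coefficient of variation was 0.105.

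Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13102 of the 19024 genes with at least 1 count, libraries were scaled by TMM, and the 2 groups were compared by the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) with Benjamini-Hochberg adjustment over the tested genes at a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values are scaled by TMM library sizes. Il22ra1 did not pass the filter, so its CPM was compared by a two-sided exact permutation test over all splits of 6 against 6, and its ratio has an exact conditional Poisson interval at 95%. Library measures were compared by the same permutation test, with Benjamini-Hochberg adjustment over 12 measures.

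Gene lists, 30 in number, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. The rule names Il22ra1, Il10rb, Stat3, Socs3, Cyb5r3, Ins1, Ins2, Pdx1, Mafa and Nkx6-1 whatever their values; the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM and groups that do not overlap, predicted genes being counted but not named; up to 4 called members of each list with the smallest p; and members of the acinar, fibroblast, leukocyte, endothelial and other islet hormone lists above 50 CPM. It named 131 genes, of which 130 had a fitted change with SEs from 0.0516 to 0.483; the values of some of these genes are not reported here. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Of the 30 lists, 27 had at least 5 tested members.

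Replicate numbers recur in both groups but are not said to pair samples, so the fit had no block, and a fit with the number as a block was an alternative. Within groups, every pair of libraries differed by more than sampling noise, the closest by a chi-square of 3.95 per degree of freedom, so none was counted as a duplicate. The other alternatives were RLE or upper-quartile scaling, DESeq2 1.42.0, limma-voom, no low-count filter, a mean of at least 1 CPM, leaving out each library in turn and, for lists, camera on ranks. After seeing the data, 4 more were added: leaving out sh-ctrl replicates 1 and 4 together, offsets from a spline (4 degrees of freedom each) on transcript length and GC content in each library, whole reads recovered from the CPM table, and scaling without Ins2, Iapp and Rn45s.

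Transcript length, GC content, untranslated regions, positions and exon overlap came from GENCODE M21 on GRCm38 (mm10). Of the 24421 symbols 23376 matched by symbol and 669 by synonym, and 376 matched none. Length, GC content and sequences were those of the reference transcript chosen for each gene, and its other transcripts were not searched. Short sequences of 6 to 8 bases in 3′ untranslated regions of at least 50 bases were related to log2 fold change in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A linear fit on log length, GC content and their squares was removed, residuals were limited to 2 in size, and genes with and without each sequence were compared by a z score where at least 30 genes held it. Figures were drawn with matplotlib 3.10.9.

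The comparison was tested on simulated data drawn from the means and library sizes of these libraries, with 200 genes changed and 13036 genes in the step. At a log2 change of -1 and 1 the edgeR test recovered 48 and 50 of 50 genes, and at -0.5 and 0.5 it recovered 40 and 41 of 50, with 9 false calls. The scan of short sequences, run on 8000 simulated genes, found a planted heptamer at z = -17.4 and gave no z below -3.28 with none planted. Both simulations drew genes independently of one another, and the first changed far fewer genes than the 6795 called in the data. They therefore do not test the scaling or the effect of correlated genes.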

Results

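Messenger RNA was measured by paired-end sequencing in Min6, a mouse cell line derived from an insulinoma that makes and secretes insulin. The cells carried an adenovirus with a hairpin against Il22ra1 (sh-Il22ra1) or a control hairpin (sh-ctrl) for 48 h and received 0.3 mM palmitate, a saturated fatty acid used to model lipid overload, for 24 h. Each group had 6 libraries, and the comparison asked how loss of Il22ra1, the ligand-binding subunit of the interleukin-22 receptor, changed transcription in palmitate-treated beta cells. Reads assigned to genes ranged from 13108494 in sh-ctrl replicate 1 to 15887448 in sh-ctrl replicate 6. In units of 1e+06 reads, the mean was 14.6 ± 0.947 (SD, n = 6) in sh-ctrl and 15.0 ± 0.463 (SD, n = 6) in sh-Il22ra1. Levels are given in CPM, reads per 1e+06 gene reads after TMM scaling. Between 15963 and 16289 genes had at least 1 read in a library. The labels do not say whether the 6 samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

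Il22ra1, the targeted gene, was lower in every sh-Il22ra1 library than in any sh-ctrl library. It lies on chromosome 4 from 135728172 to 135752140 on the plus strand in GRCm38. The 6 sh-ctrl libraries held 7 to 20 reads of it each, 74 in all, and the 6 sh-Il22ra1 libraries held 1 to 4 each, 15 in all. Its level was 0.831 CPM ± 0.256 (SD, n = 6) in sh-ctrl and 0.164 CPM ± 0.0873 (SD, n = 6) in sh-Il22ra1, a ratio of 0.197 with a 95% interval of 0.105 to 0.346 that covers counting error only. The difference had p = 0.00216 in a two-sided exact permutation test, the smallest value that 6 against 6 libraries allow. So few reads kept Il22ra1 out of the test across genes. The treatment labels of sh-Il22ra1 replicates 2 to 6 number the gene name upward, and Il22ra2, a separate gene for a soluble receptor, had 3 reads over all sh-ctrl and 2 over all sh-Il22ra1 libraries.

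Cyb5r3, which encodes cytochrome b5 reductase 3 and is named in the title of the series, fell 7.04-fold, from 578 CPM ± 43.1 (SD, n = 6) in sh-ctrl to 82.1 CPM ± 5.41 (SD, n = 6) in sh-Il22ra1. It lies on chromosome 15 from 83153494 to 83172592 on the minus strand. The log2 fold change was -2.82 with an SE of 0.0665 and an adjusted p of 8.58e-16 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the 7 tested genes among cytochrome b5 reductases and their partners, Cyb5r3 fell, Cyb5a, the electron acceptor cytochrome b5, rose by a log2 fold change of 0.65 (SE 0.0755), and 5 did not pass. The counts adjusted over the list alone were also 1 up and 1 down; the list was chosen because the title names Cyb5r3, so it is not independent evidence. As a list it had camera adjusted p = 0.939, and adjusted p = 0.954 with an estimated correlation.

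**Figure D1:**
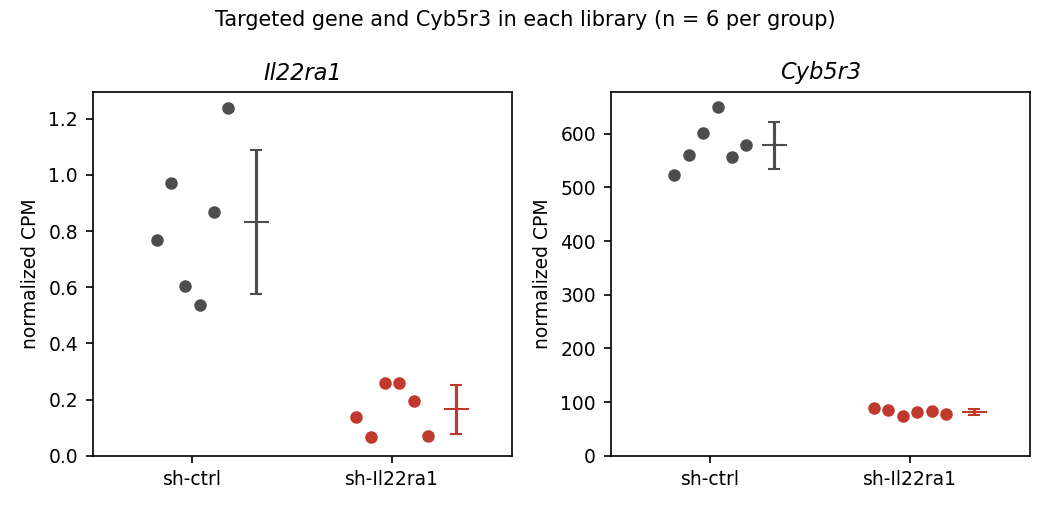
Normalized CPM (y axis) of Il22ra1 and Cyb5r3 in each of the 6 sh-ctrl (grey) and 6 sh-Il22ra1 (red) libraries; points are libraries, and the bar beside them is the mean ± SD. The sh-Il22ra1 libraries lie below every sh-ctrl library for both genes, at means of 0.164 against 0.831 CPM for Il22ra1 and 82.1 against 578 CPM for Cyb5r3.

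Across the transcriptome, 3323 genes were higher and 3472 lower in sh-Il22ra1, 51.9% of the 13102 genes tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at a threshold of 0.05. Falls were larger than rises: 479 genes fell and 158 rose by over 2-fold, and the median size of the log2 change among called genes was 0.43. In 3685 genes, or 28.1% of those tested, every library of 1 group lay above every library of the other, which chance gives for 0.216%. The first principal component held 54.4% of the variance and separated the groups. On the second, with 13.7%, sh-ctrl replicates 1 (18.2) and 4 (31.9) stood apart from sh-ctrl replicates 2 (-17.7) and 6 (-16.2), and without replicates 1 and 4, a choice made after seeing the data, 3781 genes were higher and 4146 lower.

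The largest rises among genes at a mean of 5 CPM or more whose groups did not overlap were in Slco1a5, an organic anion transporter (log2 fold change 2.08, SE 0.140), Ldhb, a lactate dehydrogenase subunit (1.82, SE 0.0915), and Saa3, an acute-phase serum amyloid (1.80, SE 0.128). Saa3 went from 7.74 CPM ± 1.89 to 26.8 CPM ± 2.89 (SD, n = 6 each). Isoc2a (1.49), Tcp11l2 (1.46), Apold1 (1.43), Lrrc51 (1.42) and the melanosome protein gene Pmel (1.39) completed the 8. Among the falls, Cyb5r3 was preceded only by Sorcs2, a sortilin-family receptor (-2.88, SE 0.212), and was followed by Rab2b (-2.72), Map6d1 (-2.33), B3gnt7 (-2.28), Rab31 (-2.19, SE 0.0726), the syntaxin gene Stx2 (-2.06) and Ppa1, a cytosolic inorganic pyrophosphatase (-2.04, SE 0.0793). Rab31 went from 78.3 CPM ± 3.88 to 17.2 CPM ± 1.74, and Ppa1 from 75.5 CPM ± 8.43 to 18.3 CPM ± 1.16 (SD, n = 6 each). Adjusted p was at most 2.81e-07 for these 8 rises and 3.29e-09 for these 8 falls in the same edgeR test. Lrrc51 shares 49.6% of its exon bases with Lamtor1 and Rab2b shares 64.0% with Tox4 or a predicted gene, so reads cannot be assigned to these genes with certainty.

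**Figure D2:**
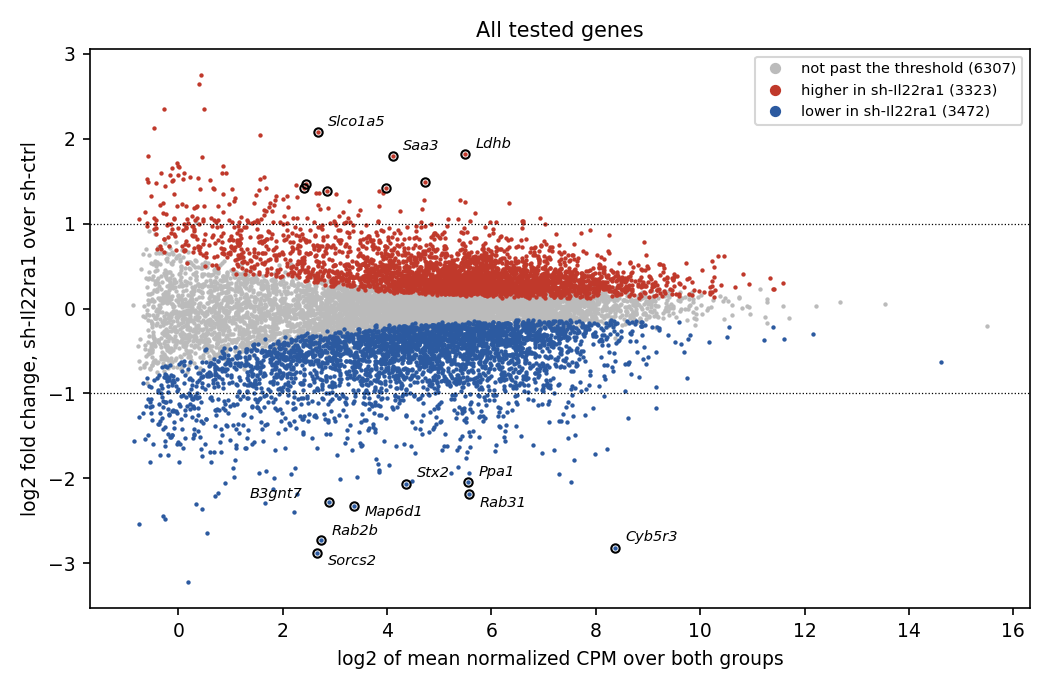
Log2 fold change in sh-Il22ra1 over sh-ctrl (y axis) against the log2 of mean normalized CPM (x axis) for the 13102 tested genes, 6 libraries per group; red points passed an adjusted p of 0.05 upward (3323), blue points downward (3472), and dotted lines mark 2-fold. Circles mark the 8 largest rises and 8 largest falls named by the fixed rule, and Cyb5r3 lies at -2.82, far above the other 7 falls in abundance.

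**Figure D3:**
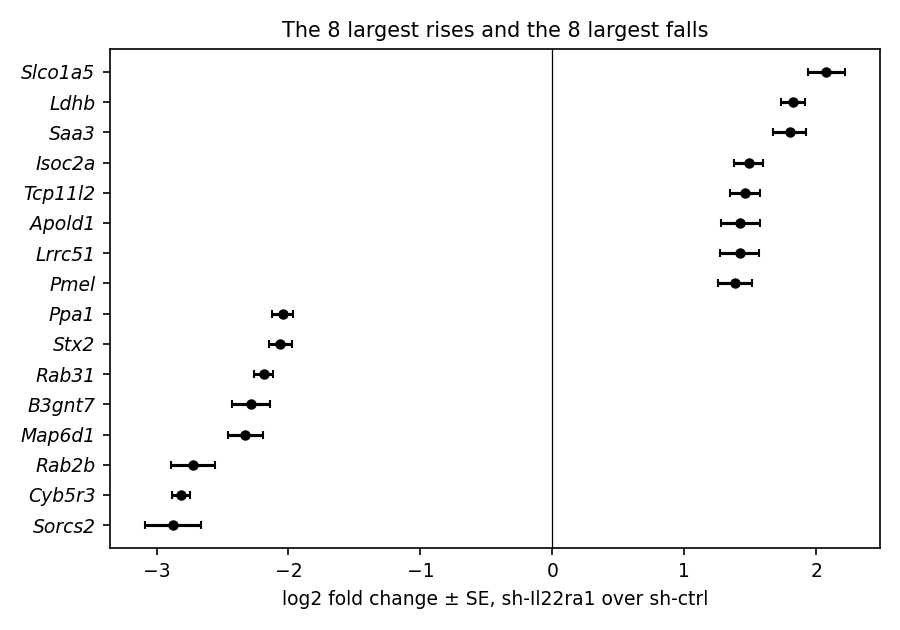
Estimated log2 fold change (x axis) with its SE for the 8 largest rises and 8 largest falls among genes at 5 CPM or more whose groups did not overlap, n = 6 libraries per group. Rises run from 1.39 (Pmel) to 2.08 (Slco1a5) and falls from -2.04 (Ppa1) to -2.88 (Sorcs2).

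Genes that mark beta-cell identity moved in both directions, with the strongest falls in Mafa, Trpm5 and Slc2a2. Mafa, a transcription factor of mature beta cells, fell from 556 CPM ± 73.8 to 227 CPM ± 16.9 (SD, n = 6 each; log2 fold change -1.29, SE 0.0813). The cation channel gene Trpm5 (-1.24), the glucose transporter gene Slc2a2 (-0.93) and Iapp, the gene of islet amyloid polypeptide (-0.63), fell too, each with adjusted p of at most 2.65e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the insulin genes, Ins1 fell (-0.36, SE 0.0850) while Ins2 gave -0.21 (SE 0.112, adjusted p = 0.123), which did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Ins2 passed that edgeR test without sh-ctrl replicate 2 (-0.28, adjusted p = 0.0278) and after correction for transcript length and GC content (-0.30, adjusted p = 0.000145), while its adjusted p reached 0.402 under other alternatives. Pdx1 gave -0.08 (SE 0.0561) and did not pass, and Nkx6-1 fell by 0.23 on the log2 scale (SE 0.0730), a call that ended after the length and GC correction (-0.08, SE 0.0668; edgeR adjusted p from 0.000155 to 0.292 over the alternatives). Of the 28 members of the list, 9 rose, 10 fell and 9 did not pass; adjusted over the list alone, 9 rose and 11 fell. The list as a whole had camera adjusted p = 0.520, and adjusted p = 0.875 with an estimated correlation.

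Of 30 genes of the insulin secretion machinery, 12 were lower, 3 higher and 15 not past the threshold, with the same counts when adjusted over the list alone. Kcnj11, the pore of the ATP-sensitive potassium channel, fell from 351 CPM ± 32.2 to 222 CPM ± 13.3 (SD, n = 6 each; log2 fold change -0.66). The calcium sensor gene Syt7 (-0.62), the SNARE gene Snap25 (-0.49) and the granin gene Scg2 (-0.37) fell as well, with SEs of 0.0637 to 0.0903 among the 4. Against all other genes the list had camera adjusted p = 0.0575, and adjusted p = 0.521 with an estimated correlation. It passed downward without sh-ctrl replicate 1, sh-ctrl replicate 4 or sh-Il22ra1 replicate 3 (camera adjusted p down to 0.0292), on ranks (0.0424), with the replicate number as a block (0.0442) and without sh-ctrl replicates 1 and 4 together (0.0216). Among genes repressed in mature beta cells, 3 of 6 tested fell: Ldha (-0.69), Myc (-0.60) and the monocarboxylate transporter gene Slc16a1 (-0.54). The count adjusted over the list alone was also 3, with camera adjusted p = 0.455, and adjusted p = 0.521 with an estimated correlation.

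Nuclear genes for subunits of the respiratory chain and ATP synthase were higher in 58 of 75 tested cases, none was lower and 17 did not pass, at a list median log2 fold change of 0.32. The list had camera adjusted p = 9.96e-09 with the preset correlation of 0.01, and adjusted p = 0.521 with the estimated correlation of 0.667. Adjusted over the list alone, 60 rose. The complex IV-associated subunit gene Ndufa4 rose from 107 CPM ± 11.4 to 196 CPM ± 17.8 (SD, n = 6 each; log2 fold change 0.88), and Cox7b (0.62), Sdhc (0.54) and Cyc1 (0.48) rose too, with SEs of 0.0673 to 0.0908 among the 4. None of the symbols listed for subunits encoded in mitochondrial DNA was among the counted genes, so these subunits could not be tested. Regulators of mitochondrial dynamics and biogenesis went both ways: Esrra, an estrogen-related receptor that drives mitochondrial genes, rose (0.94), while the fission gene Fis1 (-0.97), the mitochondrial polymerase gene Polg (-0.73) and the import channel gene Timm23 (-0.58) fell. In that list 7 of 29 rose, 11 fell and 11 did not pass, with the same counts adjusted over the list alone and camera adjusted p = 0.646 (adjusted p = 0.893 with an estimated correlation).

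Among antioxidant genes and targets of NRF2, 17 of 27 were higher, 3 lower and 7 not past the threshold; the list passed camera upward (adjusted p = 0.00382) but not with an estimated correlation (adjusted p = 0.521). Gclc, the catalytic subunit of glutamate-cysteine ligase (log2 fold change 0.70), the mitochondrial superoxide dismutase gene Sod2 (0.61) and Nfe2l2, which encodes NRF2 itself (0.52), rose, while Osgin1 fell (-0.65); SEs were 0.0568 to 0.0654. Adjusted over the list alone, 18 rose and 3 fell. Of 29 glycolysis and TCA cycle genes, 14 rose, 4 fell and 11 did not pass, also when adjusted over the list alone. The mitochondrial enzyme genes Pdhb (0.67), Suclg2 (0.60) and Idh3b (0.46) rose and Pfkl, the liver-type phosphofructokinase, fell (-0.91). That list had camera adjusted p = 0.0366, and adjusted p = 0.521 with an estimated correlation; the camera call ended without sh-ctrl replicate 5, sh-ctrl replicate 6, sh-Il22ra1 replicate 4 or sh-Il22ra1 replicate 6 (adjusted p up to 0.0666). It also ended after correction for transcript length and GC content, added after seeing the data (camera adjusted p = 0.114), although the list median was 0.15 before and 0.16 after it (SD over members 0.318 and 0.301). Camera compares a list with the other genes, and the median of all tested genes went from -0.0043 to 0.04 with this correction.

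Lipid genes showed no common direction. Of 23 tested genes of fatty acid oxidation and PPAR signalling, 7 rose, 9 fell and 7 did not pass, with the same counts adjusted over the list alone. Acadvl, very long-chain acyl-CoA dehydrogenase, rose (log2 fold change 0.63), and Ppard (-0.88), Hadh (-0.50) and Acads (-0.43) fell. Acadvl shares 42.9% of its exon bases with Dvl2, which leaves its reads uncertain. Of 33 genes of cholesterol and fatty acid synthesis, 6 rose, 12 fell and 15 did not pass (6 and 13 adjusted over the list alone). The sterol enzyme gene Msmo1 fell from 62.9 CPM ± 3.75 to 21.6 CPM ± 3.02 (SD, n = 6 each; -1.54) and Hmgcs1 fell (-0.58), while Mvd (0.84) and the sterol sensor gene Insig1 (0.61) rose. These lists had camera adjusted p of 0.947 and 0.635, and adjusted p = 0.954 for both with an estimated correlation. The mean of the fatty acid oxidation list was -0.08 and its median 0.04.

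Among targets of the integrated stress response, 12 of 24 rose, 2 fell and 10 did not pass (12 and 3 adjusted over the list alone): Fgf21, a stress-induced hormone (log2 fold change 1.11), Ddit4, an inhibitor of mTORC1 (0.89), and the amino acid transporter gene Slc7a5 (0.62) rose, and Gdf15 fell (-1.34). The list had camera adjusted p = 0.0294, and adjusted p = 0.417 with an estimated correlation. In the unfolded protein response list, 6 of 26 rose, 8 fell and 12 did not pass, also when adjusted over the list alone. Creld2 fell from 115 CPM ± 9.19 to 38.8 CPM ± 3.50 (SD, n = 6 each; -1.56), and Edem1, a factor in the disposal of misfolded glycoproteins (-1.34), and the ER chaperone cofactor gene Sdf2l1 (-0.81) fell, whereas Herpud1 rose (0.52). That list had camera adjusted p = 0.520, and adjusted p = 0.764 with an estimated correlation. Of 13 heat shock genes, 4 rose, 3 fell and 6 did not pass (4 and 4 adjusted over the list alone), with Hsph1 (0.36), Hsf1 (0.33) and Dnajb1 (0.27) higher, Hspb8 (-0.37) lower, and camera adjusted p = 0.939 (adjusted p = 0.954 with an estimated correlation). The camera direction of the heat shock list was up and its median was -0.03.

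The lists of NF-kB targets and of p53 targets passed camera upward with the preset correlation (adjusted p = 0.0230 for both) but not with an estimated correlation (adjusted p = 0.274 and 0.417). NF-kB targets and cytokines had 10 of 16 tested members up, 1 down and 5 not past the threshold, with the same counts adjusted over the list alone. Besides Saa3, the iron-binding protein gene Lcn2 (log2 fold change 1.14), the adhesion molecule gene Icam1 (0.72) and the NF-kB inhibitor gene Nfkbia (0.42) rose. Of 20 tested p53 targets, 12 rose, 3 fell and 5 did not pass, also when adjusted over the list alone. The antiproliferative gene Btg2 rose from 64.4 CPM ± 3.82 to 131 CPM ± 5.84 (SD, n = 6 each; 1.03), and Ei24 (0.76) and Perp (0.70) rose, while Ccng1, the gene of cyclin G1, fell (-1.28). Cell death regulators split, with 6 of 20 up, 7 down and 7 not past the threshold, also when adjusted over the list alone. Mlkl, the effector of necroptosis (-1.19), the apoptosis inhibitor gene Bcl2l1 (-0.35) and Diablo (-0.44) fell and Bak1 rose (0.56); Diablo and Bak1 share 40.9% and 25.5% of their exon bases with other genes. That list had camera adjusted p = 0.635, and adjusted p = 0.893 with an estimated correlation.

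**Figure D4:**
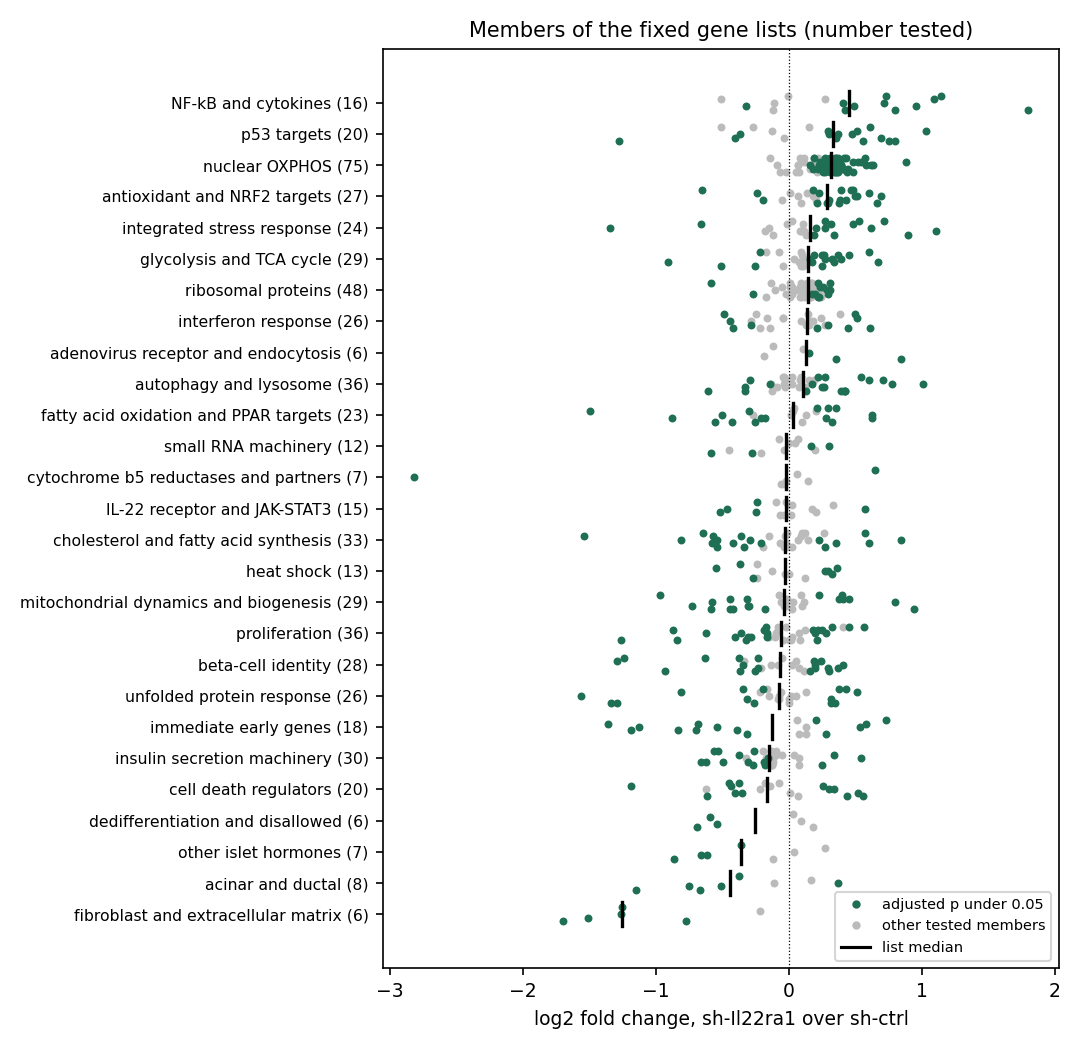
Log2 fold change in sh-Il22ra1 over sh-ctrl (x axis) of the tested members of 27 gene lists fixed before the data were examined (y axis, number tested in brackets), ordered by list median (black bar); green points passed an adjusted p of 0.05 and grey points did not. The 75 nuclear OXPHOS genes sit at a median of 0.32 with no called fall, while beta-cell identity genes spread from -1.29 to 0.41.

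Genes of the interleukin-22 receptor and its JAK-STAT3 pathway did not pass as a list: of 15 tested members 1 rose, 4 fell and 10 did not pass, also when adjusted over the list alone, with camera adjusted p = 0.873 (adjusted p = 0.954 with an estimated correlation). The kinase gene Pim1 rose (log2 fold change 0.57) and Bcl3 (-0.51), Jak2 (-0.46), Jak1 (-0.24) and the STAT3 target Socs3 (-0.24, SE 0.0625) fell. Il10rb, the second chain of the receptor, was at 23.3 CPM ± 2.24 and 23.6 CPM ± 2.11 (SD, n = 6 each; 0.02, SE 0.0817). Stat3 gave -0.07 (SE 0.0922) and did not pass; without sh-ctrl replicates 1 and 4 it gave -0.21 at adjusted p = 0.00580 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, against up to 0.994 when 1 library was left out. Of 26 tested interferon response genes, 6 rose, 4 fell and 16 did not pass (5 and 4 adjusted over the list alone), with Tap1 (0.61), Cmpk2 (0.52) and Usp18 (0.44) higher and Irf7 (-0.28) lower. Camera gave adjusted p = 0.455 for this list, and adjusted p = 0.521 with an estimated correlation.

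Immediate early genes moved in both directions. Egr1 (log2 fold change -1.18) and Arc (-0.70) fell and Junb (0.73) and Jun (0.58) rose, and in the list 5 of 18 rose, 9 fell and 4 did not pass, also when adjusted over the list alone (camera adjusted p = 0.520; adjusted p = 0.875 with an estimated correlation). Proliferation genes were mixed. Ccnd2, the gene of cyclin D2, fell from 314 CPM ± 41.6 to 131 CPM ± 6.30 (SD, n = 6 each; -1.26), the mitotic genes Kif11 (-0.87) and Mki67 (-0.84) fell, and Rrm2, a ribonucleotide reductase subunit, rose (0.56). Of 36 members 9 rose, 13 fell and 14 did not pass, also when adjusted over the list alone (camera adjusted p = 0.725; adjusted p = 0.935 with an estimated correlation).

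Of 36 autophagy and lysosome genes, 15 were higher, 5 lower and 16 not past the threshold, also when adjusted over the list alone. The list had camera adjusted p = 0.0366, and adjusted p = 0.521 with an estimated correlation. The camera call ended without sh-ctrl replicate 5, sh-ctrl replicate 6, sh-Il22ra1 replicate 2 or sh-Il22ra1 replicate 4 (adjusted p up to 0.0666). It also ended after length and GC correction (camera adjusted p = 0.0977), with a list median of 0.11 before and 0.09 after it (SD over members 0.333 and 0.347). Ulk1, the kinase that starts autophagy, rose from 64.1 CPM ± 8.54 to 129 CPM ± 9.63 (SD, n = 6 each; log2 fold change 1.01), and Atg12 (0.78), Atg16l1 (0.71) and the proton pump gene Atp6v1a (0.60) rose. Ribosomal protein genes gave 11 of 48 up, 2 down and 35 not past the threshold (0 and 1 adjusted over the list alone by edgeR). Rpl13 (0.31), Rpl27 (0.29) and Rpl3 (0.22) rose and Rpl22 fell (-0.58). Camera gave adjusted p = 0.0595, and adjusted p = 0.893 with an estimated correlation; without sh-ctrl replicate 1, sh-ctrl replicate 4, sh-Il22ra1 replicate 1 or sh-Il22ra1 replicate 3 the list passed upward, down to camera adjusted p = 0.00206. It also passed on ranks (0.0481), with the replicate number as a block (0.0442) and without sh-ctrl replicates 1 and 4 together (9.83e-06), whereas length and GC correction took its median from 0.15 to 0.06 (camera adjusted p = 0.769).

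Of 12 small RNA machinery genes, 2 rose, 2 fell and 8 did not pass, and adjusted over the list alone 1 fell and 0 rose by edgeR. Ago3 gave a log2 fold change of -0.58 (SE 0.165) at only 3.34 CPM ± 0.639 in sh-ctrl, Tnrc6a -0.28, Xpo5 0.30 and Dgcr8 0.17. The calls of Ago3 and Tnrc6a ended after length and GC correction, which took Ago3 to -0.30 (SE 0.148) and Tnrc6a from -0.28 (SE 0.0955) to -0.09 (SE 0.0721), with edgeR adjusted p = 0.0830 and 0.306. Leaving out 1 library ended the call of Tnrc6a for 3 libraries, of Xpo5 for 6 and of Dgcr8 for 8, with edgeR adjusted p up to 0.0579, 0.0690 and 0.111. Without sh-ctrl replicates 1 and 4 together, the calls of Xpo5 (0.12, edgeR adjusted p = 0.136) and Dgcr8 (0.09, edgeR adjusted p = 0.274) ended. The call of Dgcr8 also ended with no low-count filter, at a mean of at least 1 CPM and with scaling without Ins2, Iapp and Rn45s (edgeR adjusted p = 0.0693, 0.0682 and 0.0674). For Tnrc6a the libraries whose absence ended the call were sh-ctrl replicates 2 and 6 and sh-Il22ra1 replicate 2; for Xpo5 they were sh-ctrl replicates 1, 4 and 5 and sh-Il22ra1 replicates 3, 5 and 6, and for Dgcr8 these 6 and sh-Il22ra1 replicates 1 and 2. The list had camera adjusted p = 0.939, and adjusted p = 0.954 with an estimated correlation. Cxadr, the main cell-surface receptor of adenovirus, rose from 20.6 CPM ± 3.04 to 37.0 CPM ± 2.33 (SD, n = 6 each; 0.85), as did the endosomal gene Rab5a (0.35) and the integrin gene Itgb5 (0.15). Itgb5 lost its call without sh-ctrl replicate 1, 2 or 5 or sh-Il22ra1 replicate 2, 4 or 6 (edgeR adjusted p up to 0.0656). Of the 6 tested receptor and endocytosis genes 3 rose, none fell and 3 did not pass, also when adjusted over the list alone with camera adjusted p = 0.290 and adjusted p = 0.521 with an estimated correlation.

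Of the other islet hormones, Gcg, the gene of glucagon, fell from 267 CPM ± 18.1 to 147 CPM ± 5.69 (SD, n = 6 each; log2 fold change -0.86), and Npy (-0.66, from 481 CPM), Sst (-0.62, from 8.75 CPM) and Ttr (-0.36, from 975 CPM) fell; Cck gave -0.11 from 3475 CPM and did not pass, except after length and GC correction (-0.13; edgeR adjusted p from 0.0215 to 0.511 over the alternatives). Among 7 tested members 4 fell, 0 rose and 3 did not pass by edgeR, also when adjusted over the list alone (camera adjusted p = 0.109; adjusted p = 0.521 with an estimated correlation). Acinar and ductal markers had 1 of 8 up and 5 down with 2 not past the threshold, also when adjusted over the list alone: Krt7 rose (0.37, from 170 CPM), Spp1 fell (-0.37), and Krt8 gave 0.17 from 98.8 CPM. Krt8 did not pass with all libraries and passed without sh-ctrl replicate 4 (0.24, edgeR adjusted p = 0.00384) and after length and GC correction (0.21, edgeR adjusted p = 0.00517); over all alternatives its adjusted p ran from 0.000184 to 0.265. This list had camera adjusted p = 0.145, and adjusted p = 0.521 with an estimated correlation. Fibroblast and matrix genes were near the detection floor: 5 of 6 tested fell and 1 did not pass, also when adjusted over the list alone, with Col1a1 (-1.69), Col1a2 (-1.51), Thy1 (-1.25) and S100a4 (-0.77) all at means under 3 CPM in sh-ctrl (camera adjusted p = 0.0801; adjusted p = 0.521 with an estimated correlation). With the replicate number as a block the list passed downward (camera adjusted p = 0.0442). Without sh-ctrl replicate 4, Col1a2 was at -0.94. S100a4 shares 51.7% of its exon bases with a predicted gene. Cd68 (-1.84, from 22.1 CPM) and Fcer1g (-0.81) fell among 3 tested leukocyte genes and Eng (-1.30) among 3 tested endothelial and erythroid genes, 2 and 1 also when adjusted over the list alone; with under 5 tested members these lists had no camera test.

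Over the 27 lists with at least 5 tested members, 7 passed camera with the preset correlation of 0.01, all upward, and 0 passed with an estimated correlation. By fry, which tests whether the genes of a list move on balance in 1 direction without reference to other genes, 19 lists passed. The libraries also differed in the reads that were not assigned to genes. Reads without an alignment made up 14.8% ± 1.74 (SD, n = 6) of each sh-ctrl file and 9.79% ± 1.15 (SD, n = 6) of each sh-Il22ra1 file (two-sided exact permutation p = 0.00216, the smallest possible; Benjamini-Hochberg adjusted p = 0.0130 over 12 library measures), and all sh-ctrl values lay above all sh-Il22ra1 values. The 10 most abundant genes took 12.1% ± 1.14 of gene reads in sh-ctrl and 10.3% ± 0.573 in sh-Il22ra1 (SD, n = 6 each; exact permutation p = 0.00866, adjusted p = 0.0208). Reads on Ins2 and on the ribosomal RNA precursor Rn45s did not differ beyond the spread between libraries (adjusted p = 0.182 and 0.918 by the same exact permutation test).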

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

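The split by changes of over 2-fold, the split by the camera p of nuclear OXPHOS genes, the scan of short sequences and the comparison of nuclear OXPHOS members with other genes without the hexamer are tests chosen only after their results were seen. The length and GC correction and the fits without sh-ctrl replicates 1 and 4 were added after seeing the data.

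In 13 of 286 groups of 6 libraries looked at, over the named genes and 12 library measures, 1 library lay apart from the other 5 by more than Dixon's 95% critical value, a share of 4.55%; chance alone gives about 1 in 20. Of sh-ctrl replicate 4, Pfkl was at 239 CPM against 164 to 179 in the other sh-ctrl libraries, Slc2a2 at 132 CPM against 165 to 181, and Col1a2 at 3.67 CPM against 0.584 to 1.54. Of sh-ctrl replicate 6, Ndufa4 was at 84.3 CPM against 108 to 117 and Hadh at 114 CPM against 121 to 124. Of sh-ctrl replicate 3, Hsf1 was at 55.1 CPM against 48.4 to 49.8, and 15963 genes were detected against 16140 to 16207. Suclg2 was at 40.7 CPM in sh-ctrl replicate 5 against 35.6 to 37.5. Among sh-Il22ra1 libraries, Ccnd2 was at 119 CPM in replicate 6 against 130 to 137, Kif11 at 26.1 CPM in replicate 1 against 16.9 to 19.8, Dnajb1 at 113 CPM in replicate 3 against 122 to 126, and Stat3 at 191 CPM in replicate 3 against 152 to 165. Reads of low alignment quality made up 6.82% of sh-Il22ra1 replicate 2 against 3.99% to 4.79% in the others.

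In the rows that no comparison of genes used, ambiguous reads made up 2.07% ± 0.0422 of sh-Il22ra1 files and 1.87% ± 0.0410 of sh-ctrl files, and reads with multiple alignments 4.22% ± 0.112 and 3.96% ± 0.119 (SD, n = 6 each). The exact permutation p was 0.00216 and 0.00433, each with a Benjamini-Hochberg adjusted p of 0.0130 over 12 measures.

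A random grouping of these 12 libraries is argued against as the source of the number of changed genes. The splits into 6 and 6 numbered 100, drawn from 462 with the real one included. Of these, 1 called as many genes as the real 6795, the real one itself. The highest other called 3671, and it was the real grouping with 1 library of each group exchanged. No other split called any gene, further splits with 1 library of each group exchanged included. At over 2-fold the real split called 637 genes, and 1 of 100 splits called as many, again the real one. The split that called 3671 genes was the highest other, at 185. Chance differences between cultures could not be tested, since the labels do not say whether the samples were separate cultures. Chance cannot be excluded for the number of gene lists: 8 of the 100 splits, the real one included, called as many lists as the real 7, with the highest other at 8. Leaving out the real one, 85 splits called at least 1 list. For the nuclear OXPHOS list, 2 of the 100 splits gave a median as far from 0 as the real 0.32. They were the real one and the split that called 3671 genes, at 0.33. Further splits with 1 library of each group exchanged had medians of 0.20 to 0.26. A camera p as small came from 31 of the 100, with -log10 p of 9.43 in the real split and 27.1 in the highest other. The estimated correlation between members of this list was 0.667, against the preset 0.01.

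The fall of Cyb5r3 came with 479 genes lower by over 2-fold against 158 higher. Bias by transcript length or GC content is argued against as the whole cause: after correction these genes kept a median log2 fold change of -1.18 (-1.26 before) and Cyb5r3 was at -2.74. Reads shared with overlapping genes are argued against too, since 9.41% of the genes lower by over 2-fold had over 10% of their exon bases in another gene, 0.662 times (upper 95% limit 0.877) the 14.2% of other tested genes. A candidate explanation that stays open is that the guide strand of the vector hairpin bound these messengers through its seed. The heptamer ACTCACC in 3′ untranslated regions went with falls at z = -19.2. The most positive heptamer, GTGTCAC, went with rises at 6.24. That is also beyond the 4.93 reached in 100 permutations of the residuals, so it is no measure of noise, and its source was not tested. Both the Il22ra1 coding sequence and the 3′ untranslated region of Cyb5r3 hold ACTCACC. Loss of Il22ra1 itself also stays open, because the hairpin sequences were not used here, the labels do not settle whether 1 hairpin served all 6 sh-Il22ra1 samples, and no rescue was analysed here. Any other difference between the sh-ctrl and sh-Il22ra1 adenoviruses went with the groups, so its effect on any pattern cannot be told apart here.

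The rise of nuclear OXPHOS genes may have several sources. Length or GC content bias is argued against as the whole cause and may account for part: the list median went from 0.32 to 0.23 (SD over members 0.172) after correction, with 55 of 75 members higher and 3 lower (58 and 0 before). Sh-ctrl replicates 1 and 4, which stand apart on the second principal component, do not account for it. Without them the median was 0.41 with 70 of 75 higher. The opposite pair on that component, sh-ctrl replicates 2 and 6, was not left out together. With 1 library left out the median was 0.28 at the lowest. Scaling against genes that fell through seed matches would lift all genes without the hexamer CTCACC alike, and the 4881 others without it had a median of 0.11; the 63 members without it had 0.32 (SD 0.161), a difference of 0.21, so scaling may account for part and is argued against as the whole cause, while its sum with length and GC bias was not tested. Variation of these genes from library to library, seen in the splits, and loss of Il22ra1 both stay open.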

How the results depend on the processing

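Leaving out sh-ctrl replicates 1 and 4, the length and GC correction, the reads recovered from the CPM table and the scaling without Ins2, Iapp and Rn45s were chosen after seeing the data. Cyb5r3 was lower and past the threshold under all 23 alternatives (log2 fold change -2.84 to -2.74), and the CPM ratio of Il22ra1 stayed past it (log2 -2.52 to -2.18; with no low-count filter, a fitted -2.28). Il22ra1 was under the filter elsewhere, so DESeq2, limma-voom, the block and the length and GC correction did not refit it. After length and GC correction 4360 genes were higher and 3301 lower, so the larger count changed side; 89.6% of the calls were shared, 2 of them in the other direction. Genes higher and lower stayed within 1.5 times of 3323 and 3472 under all alternatives: with 1 library left out they ranged from 2881 to 3521 and from 3239 to 3970, and at over 2-fold from 147 to 171 and from 459 to 524. With no low-count filter, 315 genes in place of 158 rose by over 2-fold, as 19024 genes were tested. With an estimated correlation 0 gene lists changed in place of 7; the estimates for these 7 ran from -0.00208 (NF-kB) to 0.667 (nuclear OXPHOS), and the cause was not tested. With 1 library left out, 5 to 9 lists passed. Over 3012 comparisons of named genes with their values as reported, 31 lost and 7 gained a call, in 10 genes, and 0 reversed; over 566 of gene lists, 17 were lost, 14 gained and 0 reversed. The recovered reads gave 100% of the same calls. The data did not settle whether replicate numbers pair the libraries, and no test of pairing was run. Of 6 pairs, 3 correlated above 0.1, and 3 of 12 libraries correlated best with their own number. The replicate block gave 3463 genes higher, 3566 lower, 162 and 478 by over 2-fold, Cyb5r3 at -2.82 and 10 lists, with the insulin secretion, ribosomal and fibroblast lists added. At 1 to 4 reads per sh-Il22ra1 library, depth limits the size of the Il22ra1 knockdown to a ratio of 0.105 to 0.346.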

Other observations

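Every test in this part, the grouping of genes by short sequences included, was chosen after the fold changes were seen.

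Several falls, of beta-cell genes among them, and several rises, of stress genes among them, were found in genes whose reference transcript lacked the hexamer CTCACC in coding sequence and 3′ untranslated region. Other transcripts of these genes were not searched. Mafa (log2 fold change -1.29), Iapp (-0.63), Gcg (-0.86), Npy (-0.66), Sst (-0.62) and Ldha (-0.69) fell and Slco1a5 (2.08), Ldhb (1.82), Saa3 (1.80), Lcn2 (1.14), Fgf21 (1.11), Esrra (0.94) and Cxadr (0.85) rose among them. Of the 8 largest falls, all held the hexamer in the 3′ untranslated region: Cyb5r3, Sorcs2, Rab2b and Rab31 as part of the 8-base match, Map6d1 and B3gnt7 as part of a 7-base match, and Stx2 and Ppa1 as the hexamer alone. Of the 8 largest rises, Apold1 and Isoc2a held it. The beta-cell and secretion genes Slc2a2, Trpm5 and Kcnj11, which fell, held the hexamer in coding sequence or 3′ untranslated region. Trpm5 held only the hexamer, in coding sequence. The 1504 genes of that class had a median of 0.02, against 0.11 in genes with no match. Every named fall in the unfolded protein response, integrated stress response, heat shock and antioxidant lists held the hexamer as well. They were Edem1, Creld2, Sdf2l1, Gdf15, Hspb8 and Osgin1. Of the named rises in these lists, Gclc (0.70), Sod2 (0.61) and Hsph1 (0.36) held it too. Herpud1, Ddit4, Fgf21, Slc7a5, Nfe2l2, Dnajb1 and Hsf1 rose without it. In other lists, Ins1, Nkx6-1, Snap25, Scg2 and Hadh fell without it. Of searched genes not lower by over 2-fold, 58.9% held the hexamer, so holding it alone does not tie a fall to it.

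Across 12322 tested genes with a 3′ untranslated region of at least 50 bases, the fall grew with the length of the match. The median log2 fold change was -0.47 (quartiles -0.86 and -0.10) in 296 genes with the 8-base match, -0.24 in 1685 with a 7-base match (ACTCACC or CTCACCA), -0.08 in 1947 with the hexamer alone and 0.05 in 8394 with none. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 62.5% of the genes with the 8-base match were lower, against 20.4% of those with none. Matches in the coding sequence alone went the same way at a smaller size. Medians were -0.27 in 310 genes with the 8-base match and -0.09 in 1636 with a 7-base match. They were 0.02 in 1504 with the hexamer alone and 0.11 in 4944 with no match in either region. In 5′ untranslated regions the heptamer ACTCACC had z = -1.36, against -13.4 in coding sequence and -19.2 in 3′ untranslated regions. There, 100 permutations of the residuals gave no heptamer above 4.93 in size. Heptamers unlike ACTCACC also passed that size in 3′ untranslated regions. GTGTCAC went with rises at z = 6.24, and its 8-base form GTGTCACA at 7.14. CACCAAA, which shares no run of 5 bases with ACTCACC, was at -5.57.

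Genes with a match made up more of the falls by over 2-fold than of the rises. Of 446 searched genes lower by over 2-fold, 380 (85.2%) held the hexamer in coding sequence or 3′ untranslated region, against 58.9% of the other searched genes and 43.8% of those higher by over 2-fold. A match of 7 or 8 bases in the 3′ untranslated region was in 196 (43.9%) of them. It was in 15.0% of the other searched genes and 4.96% of those higher by over 2-fold. Of genes with the 8-base match there, 18.2% fell by over 2-fold. Their median was -0.47, against -2.82 for Cyb5r3. Among the 4944 genes without the hexamer in either region, 68 rose and 66 fell by over 2-fold, and their median was 0.11. Scaling that centres all genes near 0 raises them where genes with a match fall, so this balance is partly set by the scaling. Il22ra1 holds the 8-base match in exon 7 within its coding sequence, with the hexamer at chromosome 4 from 135750750 to 135750755 in GRCm38. Cyb5r3 holds it in exon 9 within its 3′ untranslated region, with the hexamer at chromosome 15 from 83154504 to 83154509. Of all searched genes, 3.64% hold it in the coding sequence. Such a graded relation at z = -19.2 is consistent with a hairpin guide whose bases 2 to 8 pair with ACTCACC and which was aimed at Il22ra1; the hairpin sequence was not used here, so this is a hypothesis, and a change in a microRNA with the same seed after loss of Il22ra1 was not tested. On that hypothesis part of the fall of Cyb5r3 may not need Il22ra1 at all, which a second hairpin with another seed, or a Cyb5r3 without the match, would test.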
